A study of Mus musculus with 8 samples.

How the data were processed

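The data are 8 libraries of mouse hepatocyte RNA, 4 from static culture and 4 from cells exposed to shear stress, with groups and replicate numbers taken from the sample titles. Per the labels, total RNA was extracted with TRIzol, libraries were made with phi29 reagents, and these were sequenced on the DNBSEQ platform. The submitters' processing notes name HISAT, Bowtie2 and RSEM and the mouse genome build GRCm38 (mm10). Their versions, the annotation, and whether counting used the strand of the reads are not given in the sources used here. RSEM assigns reads that match several transcripts by estimated probability, so the division of reads between near-identical genes (Hspa1a and Hspa1b, and the Serpina1, Saa, Gsta, Ugt1a and Cyp families) is uncertain, as is that between overlapping genes.

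Each deposited file gives, for the same 17276 genes, an Entrez gene ID and symbol, a read count, a TPM and an FPKM value, per the file headers. The read counts are expected counts, which the authors estimated from the aligned reads with RSEM before they were deposited. They need not be whole, and between 9.31% and 10.7% of them per library were not whole (tolerance 1e-09). The TPM and FPKM columns were also computed by the authors, per the file headers. TPM was read only to check the files and entered no test. FPKM was used for 1 alternative. Over the files, 174 genes had no count in any library. Coordinates were taken from a RefSeq table of GRCm38.p6, in which 17229 of the 17276 IDs matched, and strands for the neighbour test from GENCODE gene models of the same build.

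Expected counts were rounded to whole numbers. Genes were kept by the filterByExpr function of edgeR with the groups as its argument, which left 11747. Libraries were scaled with TMM factors, which averaged 0.926 ± 0.0369 in static and 1.08 ± 0.0433 in shear stress libraries (SD, n = 4). A two-sided exact permutation test that took the libraries as unpaired gave p = 0.0286, the smallest it allows. Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit and glmQLFTest, robust) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. Gene lists were tested on log2 CPM (prior count 2) with camera of limma 3.58.1, with a preset correlation of 0.01 and again with an estimated one, and with fry, which asks whether the genes of a list move one way on balance and compares no list with other genes. Camera p-values are two-sided and adjusted over the 37 lists fixed beforehand with at least 5 tested members. Those of lists written after results had been seen, and their fry p-values, are adjusted separately, over the 9 such lists with at least 5 tested members.

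The design, the alternatives, 43 gene lists and the rule for named genes were set before the data were examined. The rule names the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM, no overlap between groups and a symbol that is not a predicted-gene name, then up to 4 called members of each list by smallest p, or the most abundant member where none was called, and 12 genes in every case (among them Alb, Hnf4a, Klf2, Klf4, Piezo1, Egr1, Ccn1, Ccn2, Ccnd1, Cyp7a1 and Hmox1). Some genes that the rule names are not reported here. Further lists were written after results had been seen and are used only in the closing section.

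The replicate numbers were shared by both groups. After removal of the group means, libraries with the same number correlated at r = 0.679, 0.642, 0.56 and 0.467 over 8446 genes with a mean log2 CPM above 3, and the highest correlation between different numbers was -0.018. All 8 libraries correlated best with their own number, so the numbers pair the libraries. The labels do not say what a number stands for. The main fit and the exact permutation tests did not use this pairing. The biological coefficient of variation was 0.214, and 0.125 with the number as a block. For the lists fixed beforehand, blocked values are given where they change a call or move a count by more than 1.5 times. No pair of libraries within a group differed by as little as counting noise (lowest chi-square per degree of freedom 47.8), so each was counted as a sample.

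The depth was between 15067056 and 17935566 estimated counts in static and between 16225843 and 16732203 in shear stress libraries. The procedure was tested on simulated counts for the 11747 genes of this comparison, drawn from the means and dispersions of these libraries with 200 genes changed. The edgeR test recovered 23.9% of 1.5-fold, 71.6% of 2-fold and 90.9% of 4-fold changes, and 6.1% of its calls were false. DESeq2 recovered 34.3%, 79.1% and 95.5%, with 20.6% of calls false. Camera, camera with an estimated correlation and fry each found a list of 25 genes moved by 2-fold (adjusted p = 5.48e-41, 0.000203 and 9.27e-06) and called 0 of 40 random lists. Far fewer genes changed in the simulation (200) than were called in the data (5707), which makes the adjusted threshold stricter there. These shares need not hold for the data. Genes were drawn independently and without pairs of libraries, so the list tests were not tried on correlated genes.

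Alternatives were the replicate block, RLE and upper quartile factors, library totals, no filter, a filter of at least 10 CPM in 4 libraries, DESeq2 1.42.0, limma voom, limma with a trend on log2(FPKM + 1) for genes with an FPKM of at least 1 in 4 libraries, a fold of at least 1.5, removal of the 20 most abundant genes before normalisation, and omission of each library in turn. No other sample property, such as a batch or a date, is given in the labels, and none was used.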

Results

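The series measured messenger RNA in hepatocytes of male C57BL/6N mice that were kept under static conditions or exposed to shear stress, the frictional force that a moving fluid exerts on a cell surface. There were 4 libraries per group, sequenced on a DNBSEQ instrument. The labels give neither the size nor the duration of the stress, and they do not say whether the 4 libraries of a group came from separate cultures or animals. The p-values below therefore measure only the spread between these samples, which may be technical. Estimated counts summed to between 15067056 and 17935566 per library in the static group and between 16225843 and 16732203 in the shear stress group. At these totals, 3 counts correspond to between 0.157 and 0.227 CPM (counts scaled to a common library total). The files list 17276 genes, of which 11747 had enough counts to be tested. Expression is given below as mean normalised CPM ± SD (n = 4 per group). Changes are log2 fold changes of shear stress over static ± standard error, with Benjamini-Hochberg adjusted p-values from the edgeR quasi-likelihood test. Coordinates are GRCm38 positions of the whole gene, exons and introns together.

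The comparison asks which transcripts of hepatocytes differ between shear stress and static culture. Higher under shear stress were 19 of 26 genes of the actin cytoskeleton, such as Actn1 and Tpm4, 8 of 21 of the extracellular matrix, such as Fn1, and 12 of 21 of the response to transforming growth factor beta (TGF-β), such as Ccn2 and Pmepa1. Lower were 15 of 24 immediate early genes, such as Jun, Junb and Egr1, 11 of 22 heat shock genes, such as Hspa1b, and 18 of 29 genes of autophagy and lysosomes, such as Gabarapl1. Each of these lists was called as a group with a preset correlation and none with an estimated correlation (adjusted p between 0.101 and 0.688), and the TGF-β call was lost without static replicate 1, 3 or 4 or shear stress replicate 3 (between 0.0537 and 0.0648). In all, 5707 of 11747 tested genes changed, 2924 upward and 2783 downward, and 6040 were not called. A change of at least 2-fold was seen for 2033 genes, 1231 higher and 802 lower. The libraries of both groups did not overlap for 4977 of the changed genes. Non-overlap held for 45.3% of all tested genes, against 2.86% by chance for unpaired libraries. The first principal component, with 66.7% of the variance, separated the groups, with the static libraries between -66.0 and -30.5 and the shear stress libraries between 41.5 and 55.7.

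**Figure D1:**
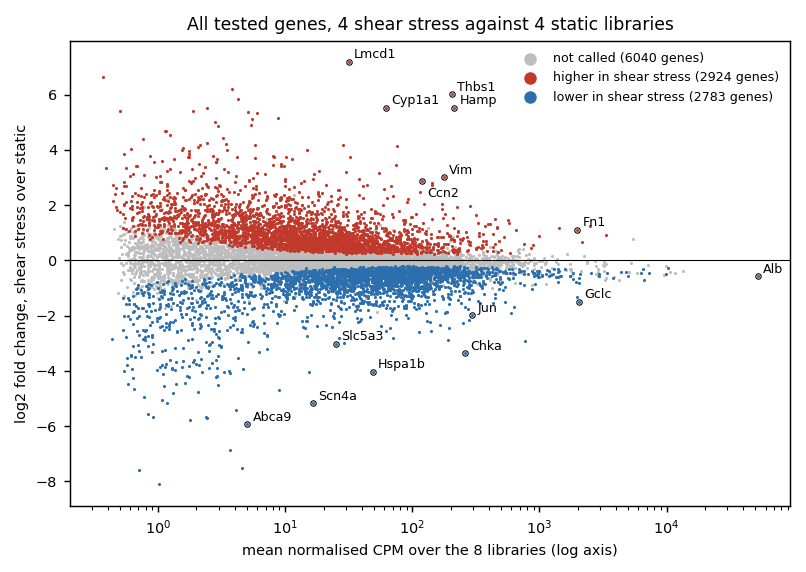
Log2 fold change of shear stress over static against mean normalised CPM (log axis) for the 11747 tested genes, 1 point per gene, coloured by call at adjusted p under 0.05. The 2924 higher genes lie mostly at low and middle abundance, and among the most abundant genes the called ones are mostly lower, with Alb at -0.57.

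The direction of change depended on abundance. Of the 3517 tested genes with a mean of at least 50 CPM, 466 were higher and 1291 lower, with a median log2 fold change of -0.21. Of the 8230 less abundant genes, 2458 were higher and 1492 lower, with a median of 0.13. The 20 most abundant genes took 21.5% ± 1.08 of the counts in static and 18.8% ± 0.839 in shear stress libraries (SD, n = 4). A two-sided exact permutation test that took the libraries as unpaired gave p = 0.0286, the smallest it allows. The share of changed genes that were higher was 51.2% with the trimmed mean (TMM) scaling factors, 64.8% with upper quartile factors, 73.0% with library totals and 73.6% with the deposited FPKM. These scalings moved the median log2 fold change by 0.14, 0.22 and 0.21, so that small changes, up to about this size, have a direction only relative to the scaling.

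The largest rise among genes of at least 5 CPM was that of Lmcd1, a LIM domain protein (Gene ID 30937; chromosome 6, 112273758 to 112330423), from 0.409 ± 0.279 to 62.8 ± 31.4 CPM (7.19 ± 0.66, adjusted p = 0.000109). Thbs1, which encodes the matrix protein thrombospondin (chromosome 2, 118111876 to 118127133), rose 64.6-fold from 6.17 ± 3.2 to 401 ± 235 CPM (adjusted p = 0.000155). Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor (chromosome 9, 57687928 to 57703824), rose 46.0-fold from 2.63 ± 0.415 to 121 ± 52.8 CPM (adjusted p = 4.79e-05). Hamp, the gene of the iron-regulating hormone hepcidin (chromosome 7, 30942368 to 30944029), rose 45.9-fold from 9.13 ± 3.98 to 417 ± 124 CPM (adjusted p = 4.79e-05). Fermt1 rose by 5.34 ± 0.62, Olfm2 by 5.16 ± 0.45, Ltbp2 by 4.89 ± 0.91 and Zfp469 by 4.19 ± 0.52, each from under 1 CPM in the static libraries. Each of these genes was higher in every shear stress library than in every static library, which the rule for naming them required.

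Among the largest falls were the choline kinase gene Chka (chromosome 19, 3851585 to 3894369), which fell 10.3-fold from 474 ± 143 to 45.9 ± 18.3 CPM (adjusted p = 9.55e-05), and the myo-inositol transporter gene Slc5a3 (chromosome 16, 92058322 to 92087473), which fell 8.09-fold from 44.5 ± 12.9 to 5.48 ± 2.1 CPM (adjusted p = 0.000128). Rbm38 fell 8.02-fold and Tent5c 7.77-fold. Hspa1b, an inducible heat shock protein 70 gene (chromosome 17, 34956429 to 34959238), fell 16.4-fold from 91.6 ± 51.9 to 5.57 ± 1.38 CPM. Its near-identical copy Hspa1a (chromosome 17, 34969359 to 34972156) changed by -3.94 ± 0.48, and the division of reads between these copies is uncertain. Of the other 5 of the 10, 4 begin within 10 kb of the end of a more abundant gene on the same strand. Iqcn, at 29.0 ± 5.02 CPM in static libraries, begins 2.84 kb after the end of Jund. Pygm begins 6.37 kb after Sf1, Mtfr2 3.16 kb after Bclaf1 and Abca9 8.62 kb after Abca6. These 4 changed by -4.04, -3.31, -3.23 and -5.94 on the log2 scale. Many genes have such neighbours. Within 50 kb upstream, 27.5% of random genes matched in abundance to the genes lower by at least 4-fold had one at least 5 times as abundant. Scn4a (chromosome 11, 106317545 to 106365559), a muscle sodium channel gene, changed by -5.18 ± 0.26, from 32.2 ± 6.02 to 0.88 ± 0.332 CPM. It lies between Cd79b (chromosome 11, 106311341 to 106314562), a B cell gene that changed by -5.41 ± 0.44, and Icam2 (chromosome 11, 106377656 to 106388139), singled out after its value was seen, which changed by -4.24 ± 0.27. Ern1 (chromosome 11, 106397620 to 106487796), a sensor of unfolded proteins, precedes all 3 on the same strand and changed by -0.63 ± 0.14. The labels do not state the strand of the libraries, so that antisense reads cannot be told from sense reads.

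**Figure D2:**
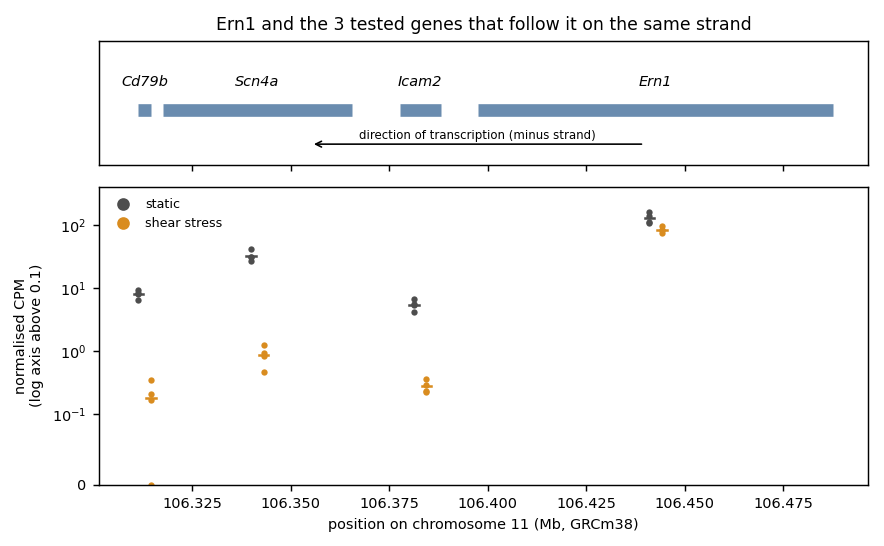
Positions of Ern1, Icam2, Scn4a and Cd79b on chromosome 11 (upper panel, Mb) and their normalised CPM per library (lower panel, log axis above 0.1; points, 4 libraries per group; lines, group means). The 3 genes behind Ern1 averaged 5.41, 32.2 and 8.02 CPM in static and 0.278, 0.88 and 0.181 CPM in shear stress libraries, whereas Ern1 averaged 129 and 83.4 CPM.

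Before the data were examined, 43 gene lists had been fixed for hepatocyte functions, mechanical and stress responses and other cell types. Of their 954 members, 778 were tested and 349 changed, 127 upward and 222 downward. That is 44.9% of list members, against 48.8% of the other tested genes. Of the 37 lists with at least 5 tested members, camera, which compares a list with all other genes, called 3 higher and 7 lower with a preset correlation of 0.01. None of the 37 was called with the correlation estimated from these libraries. With the replicate numbers as a block, the corresponding counts were 17 and 0. Fry called 16 of the 37, but not the interferon and acute phase lists that camera called. It also called lists that camera did not, such as YAP and TAZ targets (adjusted p = 0.0257), cell junctions (0.0283), circadian clock (0.0105) and NRF2 targets (0.0076). Counts adjusted over the list alone are given beside the counts over all genes where they differ.

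**Figure D3:**
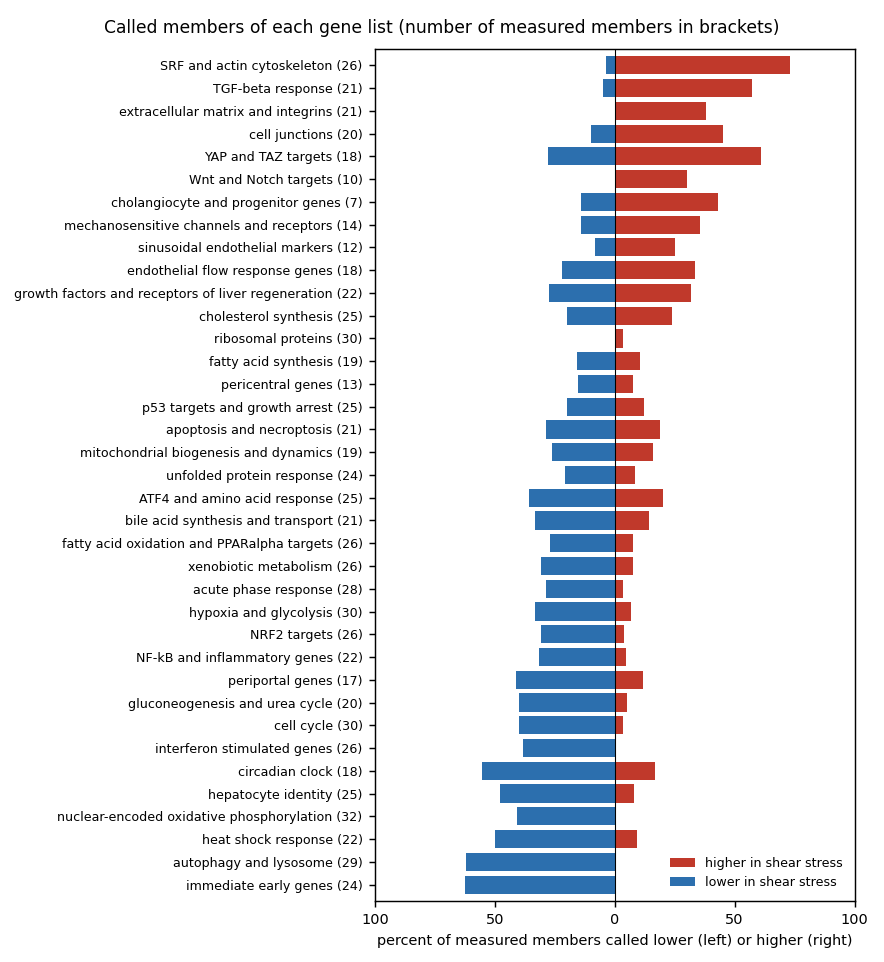
Percent of the measured members of each list called higher (right) or lower (left) in shear stress at adjusted p under 0.05, for the 37 lists with at least 5 measured members (number in brackets). SRF and actin genes stand at the upper end with 19 of 26 higher, and immediate early genes at the lower end with 15 of 24 lower.

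Genes of the actin cytoskeleton, many of them targets of serum response factor (SRF), formed the list with most rises. Of 26 measured members, 19 rose, 1 fell and 6 were not called (adjusted p = 0.00111 by camera and adjusted p = 0.688 with an estimated correlation). The intermediate filament gene Vim (chromosome 2, 13574311 to 13582826) rose 8.05-fold from 39.1 ± 17.5 to 315 ± 107 CPM, Tpm4 rose 3.61-fold to 266 ± 37.8 CPM, and the actin crosslinker gene Actn1 rose 3.77-fold to 357 ± 70.5 CPM. Rnd3, which encodes a small GTPase, was the member that fell, from 108 ± 16.6 to 27.6 ± 3.18 CPM, and 2 fell with the block. Of 21 matrix and integrin genes, 8 rose and none fell (adjusted p = 0.0211 by camera and adjusted p = 0.688 with an estimated correlation), and 13 rose and 1 fell with the replicate block. Fibronectin, Fn1 (chromosome 1, 71585473 to 71653280), rose 2.15-fold from 1249.5 ± 240.1 to 2690.2 ± 797 CPM, and the integrin genes Itga3 and Itgb6 rose 2.18-fold and 14.3-fold, the latter to only 3.25 ± 1.57 CPM. Without static replicate 3, 1 of these 21 genes fell.

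Of 21 genes of the TGF-β response, 12 rose and 1 fell, or 13 and 2 adjusted over the list alone (adjusted p = 0.0388 by camera and adjusted p = 0.688 with an estimated correlation). This camera call was lost without static replicate 1 (adjusted p = 0.0537), 3 (0.0538) or 4 (0.0648), without shear stress replicate 3 (0.0603) and with library totals (0.061). Pmepa1 rose 4.73-fold to 68.0 ± 12.1 CPM and Snai1, a repressor of epithelial genes, rose 5.1-fold to 13.6 ± 6.96 CPM. Id2 was the member that fell, from 241 ± 61.0 to 41.0 ± 11.7 CPM, and 2 fell with the block or without static replicate 1 or 4 or shear stress replicate 1, and 3 without shear stress replicate 3. Of 18 targets of YAP and TAZ, transcriptional coactivators that respond to tension and cell shape, 11 rose and 5 fell (camera adjusted p = 0.104, not called). The matricellular gene Ccn2 (chromosome 10, 24595442 to 24598683) rose 7.34-fold from 28.5 ± 16.4 to 210.0 ± 96.9 CPM (adjusted p = 0.00303), Ccn1 rose 1.92-fold from 293 ± 72.2 to 562 ± 165 CPM (adjusted p = 0.0103), and the tissue factor gene F3 rose 17.6-fold to 143 ± 77.6 CPM. Ptpn14 fell 3.04-fold to 24.1 ± 5.18 CPM.

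Of 20 cell junction genes, 9 rose and 2 fell (camera adjusted p = 0.104, 0.0461 without shear stress replicate 2, and 0.688 with an estimated correlation). Ocln rose 2.36-fold, Cldn4 5.56-fold and Cdh1, the gene of E-cadherin, 2.88-fold to 311 ± 44.9 CPM. The 2 falls, F11r and Dsp, were 1 without shear stress replicate 1 or 4 and 0 with library totals. Among 18 genes that respond to flow in endothelium, 6 rose and 4 fell, with 3 rises without static replicate 1 or 4. Their median log2 fold change was 0.38, between 0.12 and 0.60 under the other scalings and tests of all 18 genes, and -0.06 with FPKM, whose filter kept 11 of them. Pdgfa rose 4.05-fold and Pdgfb 11.8-fold, whereas Angpt2 fell 4.03-fold and Icam1 3.27-fold. Klf2, the flow-responsive transcription factor of endothelium, was at 3.69 ± 2.12 CPM in static and 2.72 ± 1.1 CPM in shear stress libraries (-0.44 ± 0.49, adjusted p = 0.485), while Klf4 fell 2.48-fold from 12.4 ± 2.68 to 5.01 ± 1.96 CPM (adjusted p = 0.00612). Of 14 mechanosensitive channels and receptors, 5 rose and 2 fell. The 5 rises were 3 without static replicate 1 or 4 or shear stress replicate 3, and 2 without shear stress replicate 4. The 2 falls were 4 with the replicate block and 1 without static replicate 4 or shear stress replicate 1, 3 or 4. Src rose 2.03-fold and Gnaq 1.6-fold, and Trpm7 fell 1.57-fold. Piezo1, a stretch-gated cation channel (chromosome 8, 122481698 to 122551329), was at 30.1 ± 6.24 CPM and 46.0 ± 13.6 CPM (0.61 ± 0.22, adjusted p = 0.0425), and its adjusted p lay between 0.0579 and 0.101 without static replicate 1, 3 or 4 or shear stress replicate 2, 3 or 4. Without shear stress replicate 3 its log2 fold change was 0.39.

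**Figure D4:**
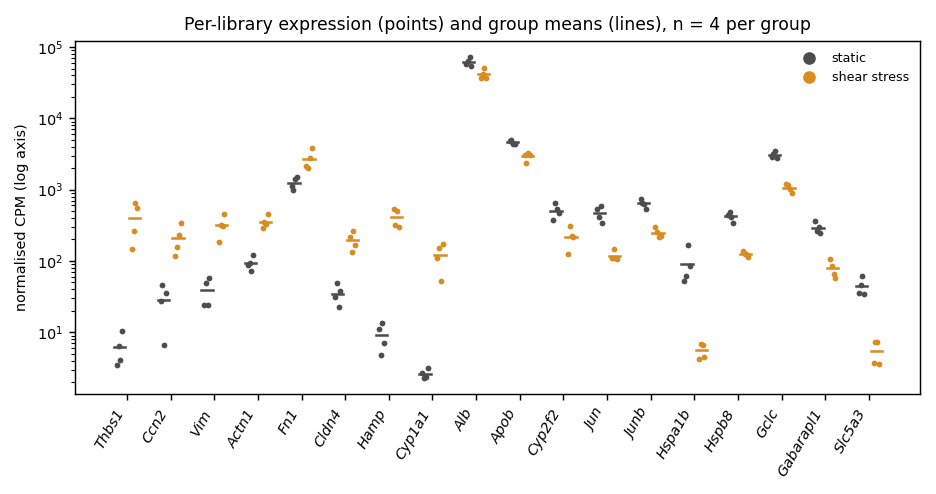
Normalised CPM (log axis) of 18 genes in each library (points) with group means (lines), 4 static and 4 shear stress libraries. The groups do not overlap for any of these genes, with Thbs1 averaging 6.17 CPM in static and 401 CPM in shear stress and Gclc averaging 3046 and 1069 CPM.

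Of 25 hepatocyte identity genes, 12 fell, 2 rose and 11 were not called, with 14 falls and 2 rises adjusted over the list alone (adjusted p = 0.0324 by camera and adjusted p = 0.688 with an estimated correlation). With the block 18 fell and 4 rose, and with library totals 5 fell and 4 rose. The camera call was lost without static replicate 3 (adjusted p = 0.122) or shear stress replicate 2 (0.0605). Alb (chromosome 5, 90460870 to 90476602) was at 62211 ± 8131 CPM in static and 41827 ± 7151 CPM in shear stress libraries (-0.57 ± 0.15, adjusted p = 0.0121, and 0.0751 with library totals). Apob fell 1.57-fold from 4614 ± 344 to 2937 ± 417 CPM, Fgg fell 1.58-fold, and the liver transcription factor gene Foxa1 fell 2.69-fold to 9.64 ± 1.74 CPM. Serpina1a also fell, 1.39-fold, but shares reads with close paralogs. The rises were those of Foxa3 and Nr5a2, named after their values were seen. Hnf4a, the master regulator of hepatocytes (chromosome 2, 163506811 to 163572907), was at 163 ± 42.7 CPM and 179 ± 28.2 CPM (0.13 ± 0.19, adjusted p = 0.59). Of 17 periportal genes 7 fell and 2 rose, with 4 falls without shear stress replicate 4, 3 falls and 3 rises with library totals, and 1 rise without shear stress replicate 2 or 4 (camera adjusted p = 0.151, 0.0349 with the block, 0.0466 with library totals, and 0.688 with an estimated correlation). Cyp2f2 fell 2.32-fold from 507 ± 116 to 219 ± 76.9 CPM and Pigr fell 1.92-fold. Of 13 pericentral genes 2 fell and 1 rose, and none of them was called over the list alone. With library totals or upper quartile factors none fell and 1 rose. With the block 8 fell and 2 rose, 1 fell without static replicate 1 or 4 or shear stress replicate 2 or 4, and 0 rose without static replicate 2 or 4 or shear stress replicate 1, 3 or 4.

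For 4 lists of liver metabolism the balance of falls and rises depended on the scaling, and camera called them only in some settings. With TMM factors, falls and rises numbered 7 and 3 of 21 for bile acid genes, 8 and 2 of 26 for xenobiotic metabolism (7 and 2 adjusted over the list alone), 8 and 1 of 20 for gluconeogenesis and the urea cycle, and 7 and 2 of 26 for fatty acid oxidation. With the block, the falls numbered 12, 20, 13 and 17, rises of gluconeogenesis and urea cycle genes numbered 3, and camera called all 4 lists (adjusted p = 0.0466, 0.00317, 0.00619 and 0.0128). The block calls were lost with an estimated correlation (adjusted p = 0.603, 0.519, 0.519 and 0.519). With library totals falls and rises numbered 1 and 4, 0 and 2, 5 and 3, and 2 and 3. Called rises thus outnumbered called falls in all of these lists but gluconeogenesis and the urea cycle. Camera called all but the bile acid list there (xenobiotic metabolism 0.0403, gluconeogenesis and the urea cycle 0.0177, fatty acid oxidation 0.0425). The median log2 fold changes of these called lists stayed below 0 (-0.233, -0.389 and -0.171), against 0.216 for all tested genes. With upper quartile factors bile acid genes (2 and 3) and fatty acid oxidation (2 and 3) also had more rises than falls. Camera also called xenobiotic metabolism without static replicate 2 (0.0361) or shear stress replicate 1 (0.0372), gluconeogenesis and the urea cycle without static replicate 2 (0.0298) or 4 (0.0371) or shear stress replicate 1 (0.0372), and fatty acid oxidation without static replicate 2 (0.0361). With an estimated correlation, all 8 libraries and TMM factors, these lists were not called (adjusted p = 0.688, 0.688 and 0.761). Without a single library, falls numbered 2 to 4 for bile acid genes without static replicate 1, 3 or 4 or shear stress replicate 1, 2 or 4, and 2 to 5 for xenobiotic genes without static replicate 1 or 3 or shear stress replicate 2 or 4. Rises of xenobiotic genes numbered 1 without static replicate 2 or 3 or shear stress replicate 1 or 3. Falls numbered 5 for gluconeogenesis and the urea cycle without static replicate 3, and 3 or 4 for fatty acid oxidation without shear stress replicate 1, 2 or 4. Rises of gluconeogenesis and urea cycle genes numbered 3 without static replicate 3 and 0 without static replicate 1 or 4. Slc27a5, the bile acid conjugating ligase gene, fell 1.69-fold from 354 ± 30.9 to 209 ± 22.2 CPM, whereas the sterol hydroxylase gene Cyp8b1 rose 3.16-fold to 26.6 ± 4.03 CPM. Otc, of the urea cycle, fell 1.67-fold, whereas the lipase inhibitor gene Angptl4 rose 3.23-fold to 162 ± 48.0 CPM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 0 to 2 counts per library and was not tested. Cholesterol synthesis genes were divided, with 6 of 25 higher, including Hsd17b7 at 2.7-fold, and 5 lower, including Pmvk. With library totals 11 were higher and 2 lower. Of 19 fatty acid synthesis genes 2 rose, Gpam 2.1-fold and Fads2 1.84-fold, and 3 fell, of which none fell adjusted over the list alone. The falls were 0 or 1 without static replicate 1 or 3 or shear stress replicate 1, 2 or 4, and 5 rose and 10 fell with the block. With library totals 4 rose and none fell, and with upper quartile factors 3 rose and none fell.

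Immediate early genes are switched on within minutes of a stimulus. Of 24, 15 fell and none rose, or 17 falls adjusted over the list alone (adjusted p = 7.95e-05 by camera and adjusted p = 0.101 with an estimated correlation), and 1 rose with the block, with library totals or without static replicate 2. Jun (chromosome 4, 95049036 to 95052222) fell 3.97-fold from 469.9 ± 110.5 to 118 ± 20.4 CPM (adjusted p = 8.72e-05), Junb fell 2.57-fold from 641 ± 79.5 to 249 ± 37.0 CPM, Maff fell 3.16-fold, Ier2 fell 2.14-fold and Egr1 (chromosome 18, 34861207 to 34864956) fell 1.89-fold from 451 ± 84.5 to 239 ± 36.6 CPM (adjusted p = 0.00128). Of 22 heat shock genes 11 fell, or 12 over the list alone, and 2 rose (adjusted p = 0.0211 by camera and adjusted p = 0.688 with an estimated correlation). Hspb8 fell 3.37-fold from 423 ± 63.0 to 125 ± 11.1 CPM, and Hspa4 rose 1.8-fold from 378 ± 29.3 to 681 ± 74.0 CPM. With library totals 7 heat shock genes fell and 4 rose, with a median log2 fold change of -0.07 in place of -0.29, and without static replicate 1 or shear stress replicate 4, 1 rose.

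Of 29 genes of autophagy and lysosomes, 18 fell, or 19 over the list alone, and none rose (adjusted p = 0.000172 by camera and adjusted p = 0.387 with an estimated correlation), with 7 falls under library totals. Gabarapl1 fell 3.69-fold from 290.0 ± 50.2 to 78.6 ± 21.8 CPM, Map1lc3b, the gene of the autophagosome protein LC3B, fell 1.71-fold, and Tfeb, a regulator of lysosomal genes, fell 2.38-fold to 5.88 ± 0.801 CPM. Of 26 targets of NRF2, which controls antioxidant genes, 8 fell and 1 rose, or 7 and 0 over the list alone. The rise was lost without static replicate 1, 2 or 4 or shear stress replicate 2, 3 or 4. Falls numbered 15 with the block (camera adjusted p = 0.0135, and 0.603 with an estimated correlation), and with library totals 4 fell and 3 rose. Camera called the list without static replicate 1 (0.0458) or 2 (0.0363) or shear stress replicate 1 (0.0386) and with library totals (0.041), but not with an estimated correlation (0.688). Gclc, a subunit of the rate-limiting enzyme of glutathione synthesis (chromosome 9, 77754535 to 77794489), fell 2.85-fold from 3046 ± 307 to 1069 ± 137 CPM (adjusted p = 5.50e-05), and Gclm fell 1.89-fold. Hmox1 was at 225 ± 63.8 CPM and 121 ± 94.3 CPM (-0.90 ± 0.46, adjusted p = 0.139). It was lower at adjusted p = 0.00491 with the block and at 0.00196 without shear stress replicate 1, when its log2 fold change was -1.59.

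Of 26 interferon stimulated genes 10 fell and none rose (adjusted p = 0.00827 by camera and adjusted p = 0.688 with an estimated correlation). Fry did not call this list (adjusted p = 0.0811). With the block 18 fell and 1 rose, with library totals 4 fell, and 6 fell without static replicate 2 or shear stress replicate 3 or 4. The macrophage marker Mpeg1 fell as well, 2.47-fold. Stat2 fell 2.11-fold and Usp18, a brake on interferon signalling, fell 3.15-fold. Of 28 acute phase genes 8 fell and 1, Hamp, rose (adjusted p = 0.0388 by camera and adjusted p = 0.688 with an estimated correlation), with 19 falls and 2 rises in the block fit. That camera call was lost without static replicate 1 (adjusted p = 0.0885) or 4 (0.0577) and without shear stress replicate 2 (0.104) or 3 (0.0664). Fry did not call the acute phase list (adjusted p = 0.12). Socs3, a feedback inhibitor of cytokine signalling, fell 4.24-fold and C3 fell 1.65-fold from 8214 ± 969 to 4979 ± 591 CPM. Of 22 NF-κB and inflammatory genes 7 fell and 1 rose, with 3 rises in the block fit and 2 without static replicate 4, and camera called the list only without shear stress replicate 1 (0.0224) and with library totals (0.0403) among the settings run, and not with an estimated correlation (0.708). Rela fell 1.74-fold and Nfkbiz 2.4-fold.

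Of 32 nuclear-encoded genes of oxidative phosphorylation 13 fell and none rose, but only 2 fell adjusted over the list alone (adjusted p = 0.0106 by camera and adjusted p = 0.688 with an estimated correlation). The list median of -0.23 was close to the -0.21 of all tested genes of at least 50 CPM, of which 1291 of 3517 fell. Camera compared this list with all other genes, and no abundance-matched lists were drawn for it. The falls were small, as for Atp5c1 (-0.42) and Sdhd (-0.43), and neither of these was called with library totals. With library totals none fell, 1 rose and the camera call was lost (adjusted p = 0.187). The falls numbered 3 or 4 without shear stress replicate 1, 2 or 4, 6 without static replicate 3, and 8 without static replicate 1 or shear stress replicate 3. Of 18 circadian clock genes 10 fell and 3 rose, or 12 and 3 over the list alone (camera adjusted p = 0.0597). Camera called this list with the block (0.0159), with library totals (0.0125) and without static replicate 2 (0.0493) or 4 (0.0444), but not with an estimated correlation (0.688, and 0.519 with the block). Clock fell 2.78-fold from 75.5 ± 12.1 to 27.1 ± 3.81 CPM, Nr1d2 fell 2.77-fold and Nr1d1 fell 2.26-fold, whereas Bhlhe40 rose 2.47-fold.

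Stress lists other than these went both ways. Of 25 ATF4 and amino acid response genes 9 fell, including Ppp1r15a at 3.64-fold lower and Gdf15 at 2.17-fold lower, and 5 rose, including Trib3 at 2.51-fold and Ddit4 at 2.07-fold. Their median was -0.15, and 0.08 with library totals. Of 24 unfolded protein response genes 5 fell, including Atf6, from 183 ± 24.1 to 72.1 ± 7.87 CPM, and 2 rose, including Xbp1 at 1.67-fold. With library totals or upper quartile factors 3 fell and 4 rose, and 4 rose without static replicate 3. Of 30 hypoxia and glycolysis genes 10 fell, or 9 over the list alone, including Vegfa at 1.81-fold, and 2 rose, Hk2 to 4.31 ± 2.33 CPM and Slc2a1 1.65-fold, with 5 falls and 4 rises under library totals and 4 rises in the block fit. Of 25 p53 and growth arrest genes 5 fell, including Mdm2, and 3 rose, with 3 falls without static replicate 2 or shear stress replicate 3. With the block 9 fell and 5 rose, with library totals 3 fell and 7 rose, and with upper quartile factors 3 fell and 5 rose. Of 21 apoptosis and necroptosis genes 6 fell, including Mcl1 at 1.76-fold, and 4 rose, including Casp8 at 2.22-fold, with 7 rises in the block fit. The falls numbered 2 or 3 without static replicate 2 or any single shear stress library. With library totals 2 fell and 6 rose, and with upper quartile factors 2 fell and 4 rose.

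Of 30 cell cycle genes 12 fell, or 9 over the list alone, and 1 rose. The falls numbered 5 or 6 without static replicate 3 or shear stress replicate 1, 3 or 4, and 5 with library totals. Rises numbered 2 without static replicate 1, 4 without static replicate 2 or with the block, and 3 with library totals, where camera called the list (0.0466, and 0.761 with an estimated correlation and TMM factors). The rise was that of Ccnd1, the gene of cyclin D1 (chromosome 7, 144929931 to 144939831), 5.34-fold from 0.994 ± 0.226 to 5.3 ± 0.955 CPM (adjusted p = 0.000109). Ccnb2 and Cdc6 changed by -3.89 and -2.04 on the log2 scale from 5.46 ± 1.04 CPM and 2.48 ± 0.426 CPM, and begin 3.88 and 2.76 kb after the end of a more abundant gene on the same strand. Of the 12 that fell, 5 have such a neighbour within 50 kb. Of 22 growth factors and receptors of liver regeneration 7 rose and 6 fell, or 7 and 7 adjusted over the list alone and 7 and 9 with the block. Igf1 rose 2-fold from 222 ± 18.3 to 444 ± 28.3 CPM. Fgfr4, a fibroblast growth factor receptor gene, rose 4.64-fold to 43.0 ± 9.89 CPM, whereas Il6ra fell 2.15-fold. Of 19 genes of mitochondrial biogenesis and dynamics 5 fell and 3 rose, or 4 and 2 adjusted over the list alone, and with library totals 3 fell and 6 rose. Of 7 cholangiocyte and progenitor genes 3 rose, including Cldn4, and 1 fell, with 5 rises in the block fit and 2 falls without static replicate 3. Of 10 Wnt and Notch targets 3 rose, including Notch2 at 1.72-fold, and none fell, and only 1 rose over the list alone. That count was also 1 without static replicate 2 or 4 or shear stress replicate 1, 3 or 4, and 1 fell without shear stress replicate 1. Of 30 ribosomal protein genes 1, Rpl3, was called higher (adjusted p = 0.0243). None was called over the list alone or without static replicate 1, 3 or 4 or shear stress replicate 2 or 4, and 1 fell with the block. With library totals 3 were higher, the median log2 fold change was 0.19 in place of -0.03, and that of Rpl3 was 0.49 in place of 0.27.

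Markers of other liver cells were mostly near the floor. Of the macrophage markers 3 were tested and 1 fell, Mpeg1, from 137 ± 18.5 to 55.4 ± 4.97 CPM, and 2 fell over the list alone, with the block or without static replicate 4. The summed CPM of the 17 listed macrophage markers averaged 514 ± 71.2 in static and 339 ± 54.1 in shear stress libraries (two-sided exact permutation test without the pairing, p = 0.0571). Of 12 sinusoidal endothelial markers 3 rose, among them Stab1 at 14.2 ± 8.79 CPM and Flt4 at 8.54 ± 1.8 CPM, and Pecam1 fell 5.35-fold to 1.87 ± 1.38 CPM, with 2 falls in the block fit. Pecam1 begins 29.7 kb after the end of the abundant gene Ddx5, and 27.5% of the random genes above had such a neighbour within 50 kb. The endothelial sum was 41.4 ± 15.7 and 53.2 ± 24.6 CPM (exact permutation test without the pairing, p = 0.486). Of 4 stellate cell and fibroblast markers none was called, and 1 rose and 1 fell with the block, with the most abundant, Ecm1, at 17.0 ± 8.03 CPM and 23.0 ± 11.9 CPM (adjusted p = 0.499, and 0.0127 with the block). The lymphocyte markers Cd79a and Cd79b, the 2 tested, both fell, and Cd79a, at 1.93 ± 0.174 CPM in static libraries, begins 7.58 kb after Rps19. Its log2 fold change of -3.88 was -6.18 without shear stress replicate 2. Neither of the 2 tested erythroid markers was called, with Tfrc at 51.5 ± 8.72 CPM and 53.1 ± 7.93 CPM, but 1, Alas2, was lower with the block (adjusted p = 0.00201), singled out after its value was seen. Of the nuclear retained RNAs only Snhg11 was tested (adjusted p = 0.512, and 0.0357 with the block), and the mitochondrially encoded genes were not analysed here.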

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

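The tests of abundance-matched lists, the hepatocyte share, mesenchymal cells, tonicity, the scaling of heat shock genes and handling were chosen only after the result was seen. A sample far from the others of its group was found in 18 of 346 groups of 4 values (5.2%), where chance gives about 1 in 20. These were, in normalised CPM, Iqcn at 4.49 in shear stress replicate 2 (others 0.566 to 1.04) and Chka at 687 in static replicate 1 (382 to 430.4). Serpina1a was at 3618 in static replicate 3 (3344 to 3369), Cyp27a1 at 217 in static replicate 2 (279 to 292) and Gsta3 at 189 in shear stress replicate 4 (235 to 242). Jun was at 149 in shear stress replicate 2 (none above 110.3), Cmpk2 at 7.81 in shear stress replicate 1 (4.23 to 4.50) and Iigp1 at 383 in static replicate 2 (236 to 257). Ppp1r15a was at 105 in shear stress replicate 1 (70.3 to 74.4), Igf1 at 195 in static replicate 2 (228 to 234) and Mcl1 at 214 in shear stress replicate 1 (173 to 176). Pecam1 was at 3.94 in shear stress replicate 1 (1.10 to 1.27), Flt4 at 5.58 in static replicate 4 (2.73 to 3.03) and Cd79a at 0.417 in shear stress replicate 2 (0 to 0.0577). Klf2 was at 1.10 in shear stress replicate 3 (none below 3.12) and Hmox1 at 261 in shear stress replicate 1 (63.1 to 91.7). Static replicate 3 had 15067100 estimated counts (others 17445100 to 17935600), and shear stress replicate 2 had a TMM factor of 1.15 (1.06 to 1.07). Of the 18, 5 lay in shear stress replicate 1 and 4 in shear stress replicate 2.

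Of the 35 splits of the 8 libraries into groups of 4, only the real one gave as many as 5707 changed genes. The highest other split gave 4. Every other split mixes static and shear stress libraries, which widens the spread within its groups, so few calls there say little about chance. Among the 8 splits that part all 4 pairs of replicate numbers, the real one included, the highest other gave 0. With only 8 such splits, this comparison cannot by itself exclude chance.

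Lower hepatocyte identity genes in shear stress libraries had a median log2 fold change of -0.45. With library totals the median was -0.22 (95% bootstrap interval over the list members -0.34 to -0.13). This interval takes the members as independent and leaves out the spread between libraries, as do the other intervals of list medians in this section. Within this limit, the values argue against scaling as the whole cause. A smaller share of hepatocytes alone would lower all members alike, but for 7 of 25 the 95% interval excluded the list median, 6 above and 1 below it; this test replaced a first version on marker sums of other cell types, set aside after its result because its deciding genes were near the floor. A general fall of abundant genes remains open, since the list median lay at percentile 2.56 of 10000 abundance-matched lists, just inside their 95% range of -0.45 to -0.02. A smaller hepatocyte share beside changes of single genes, or an effect of shear stress on hepatocyte function, may also contribute.

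For the higher immediate early and heat shock genes in static libraries, scaling is argued against as the whole cause for the immediate early list. Its median with library totals was -0.66 (95% bootstrap interval over the members -1.45 to -0.19). Scaling stays open for the heat shock list, with 7 members lower and 4 higher under library totals. Its median there was -0.0665 (95% bootstrap interval over the members -0.40 to 0.10). A response to high tonicity in the static cultures, for example from evaporation, is a candidate explanation. Of 8 measured tonicity genes not seen among the largest changes, 5 were lower in shear stress and 1 higher. Their median was -1.12 and their mean -0.38, while 2783 of all 11747 tested genes were lower. The list was called by camera (adjusted p = 0.0303) and fry (adjusted p = 0.000356), but not with an estimated correlation (adjusted p = 0.229). These p-values are adjusted over the lists written after results had been seen, of which this is 1. Handling of the static dishes before lysis cannot be told apart from the condition, since 0 labels give a sampling time or order. An effect of shear stress itself stays open and untested.

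Of the higher actin cytoskeleton, matrix and YAP target genes in shear stress libraries, the actin list had a median of 0.998 with library totals. The 95% bootstrap interval over its members was 0.74 to 1.58, and the median with TMM factors was 0.78. Library totals moved log2 fold changes upward, by 0.22 at the median, so this test could not have removed the rise. It therefore does not decide on scaling. The matrix and YAP lists had medians of 1.02 and 0.90 with library totals, without an interval. Mesenchymal cells among the hepatocytes are argued against as the source: their matrix genes summed to 4.55 CPM in static and 2.97 CPM in shear stress libraries, 1.07% of the rise of Vim by 276 CPM. A response of the hepatocytes to shear stress is a candidate explanation, found and examined on the same data, and differences in attachment or cell density between the culture formats may act the same way.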

How the results depend on the processing

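Library totals with the block, library totals for list tests and the list-level scalings were chosen after seeing the data. The 5707 changed genes numbered between 4002 (at least 10 CPM) and 7374 (library totals with the block) under the alternatives other than a fold of at least 1.5 (3947), and calls shared with the block (5695) or library totals (4463) had the same direction. Higher genes (2924) rose to 5080 with library totals and the block. Lower genes (2783) numbered 1539 with library totals, 1315 with FPKM and 1744 at a fold of at least 1.5, which calls fewer genes by construction. Of 37 lists, camera called 10, and 17 with the block, 16 with library totals and 0 with an estimated correlation, while fry called 16; the cause was not tested. Without 1 library, changed genes ranged from 4660 to 5518, higher from 2436 to 2841, lower from 2224 to 2681, called list members (349) from 269 to 336 and called lists from 8 to 15. Of 2366 values of 169 named genes under alternatives, 2287 kept direction and side of the threshold, 75 became weaker and 4 stronger, and 0 reversed. Most of these genes were named for large changes or small p-values in the same data, so this stability was partly built in. Of 444 list tests, 384 kept both, 24 became weaker and 36 stronger, and of 1032 list counts 853 stayed within 1.5 times. Of simulated 1.5-fold changes 23.9% were recovered, in a simulation with far fewer changed genes than were called here. Smaller changes were not simulated.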

Other observations

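The lists in this part and the tests of upstream neighbours, BMP and SMAD signalling and STAT3 signalling were chosen only after the result was seen. Adjusted p-values of lists in this part are over the 9 lists chosen after the result was seen, not over the 37 fixed beforehand. Of 24 ribosome biogenesis genes, 16 were higher in shear stress and none lower, 18 with library totals (adjusted p = 0.000519 by camera and adjusted p = 0.397 with an estimated correlation), with Nop56 at 1.27 and Rrp1b at 2.32, both chosen after their values were seen. Of 27 circulating protease inhibitors and complement genes, 19 were lower (20 adjusted over the list alone) and none higher, with 9 lower under library totals (adjusted p = 3.32e-05 by camera and adjusted p = 0.229 with an estimated correlation), with summed CPM of 20159 ± 289.8 in static and 13110.0 ± 594 in shear stress libraries. Of 19 aminoacyl-tRNA synthetases 3 were higher and 3 lower (2 and 3 adjusted over the list alone), and 7 higher and none lower with library totals. Of 5 tonicity genes seen among the large changes, all 5 were lower, including Slc5a3 at -3.02, which does not test the idea.

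Transcripts that run on past the end of a gene into the next one may account for part of the largest falls, such as those of Scn4a, Cd79b and Icam2 behind Ern1, from which the idea came. Icam2 meets the neighbour rule below through Ern1, but Scn4a and Cd79b do not. These, farther from Ern1, were more abundant in static libraries (32.2 and 8.02 CPM) than the nearer Icam2 (5.41 CPM). Of 207 genes lower by at least 4-fold, without 8 whose neighbours had been looked at before (a first run had left out 6 of these), 47.8% have a same-strand gene at least 5 times as abundant that ends within 50 kb upstream. Random genes of like abundance gave 27.5% (95% range 22.2 to 33.8), the downstream side of the same genes 20.8%, and 290 genes higher by at least 4-fold 26.6%. Read-through after osmotic or heat stress is background knowledge and was not measured here, and with the strand of the libraries not stated these reads were not examined directly.

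For Cyp1a1, activity of the aryl hydrocarbon receptor would raise its other targets, but 2 of 8 measured ones were higher and none lower, and none was called over the list alone. With the block 2 were higher and 5 lower. For Hamp, signalling by BMP and SMAD would raise its targets, of which 3 of 11 were higher and 1 lower. Their median log2 fold change was 0.48, and 0.72 with library totals, with 7 of 11 above 0 with the block and 9 with library totals, while their summed CPM averaged 372 ± 36.1 in static and 323 ± 33.8 in shear stress libraries (fry adjusted p = 0.00278; adjusted p = 0.309 by camera and adjusted p = 0.397 with an estimated correlation), so that this explanation stays open. Signalling by the IL-6 family and STAT3 would raise acute phase targets, of which 0 of 16 were higher and 5 lower, or 13 lower with the block. These values argue against a broad rise of the receptor's targets and of the STAT3 targets, and a gene-specific change of Cyp1a1 or Hamp stays open.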
